A study of Caenorhabditis elegans with 208 samples.

How the data were processed

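Samples were 208 recombinant inbred advanced intercross lines of Caenorhabditis elegans, from a cross of the strains N2 and CB4856, grown at 20 °C on the bacterial strain OP50 and harvested as young adult hermaphrodites, per the labels. Each line had 1 array, hybridised with a common reference pooled from mixed strains and stages of N2 and CB4856. Strain RNA was in Cy5 for 109 lines and in Cy3 for 99, per the titles of the samples. No paired analysis was possible because each line had 1 array, so the lines themselves were the replicates of each allele.

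The deposited array files are Agilent Feature Extraction output, version 9.1.3.1 for 168 arrays (scan series A) and 9.5.3.1 for 40 arrays (scan series B). They hold, per the file headers, the mean intensity of each spot in both channels and the median intensity of its local background, with no normalisation, and flags of the software. The same deposited files hold a log10 ratio of the red over the green processed signal, made by Feature Extraction with spatial detrending, surrogate signals for dim spots and dye normalisation, per the file headers. The deposited genotype table holds letters as other values, 1 per line and marker, for 1455 markers, with positions on WormBase release ws185 per the file headers. The authors' file gives no key to the letters. B was read as N2 and H as CB4856, and 201 of 302640 cells with the letters N or T were treated as missing and filled by interpolation between neighbouring markers. Probe coordinates were in the 40 newer files only, and the genome build behind them is not given in the sources used here. Of 20401 probes, 19057 (93.4%) matched a gene of the reference table, 19054 of them on the same chromosome, and the 99th percentile of the distance from a probe to its gene was 8.0 kb.

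The channel labels of every sample name the opposite dye to the titles. Titles were used for the direction of all values. In a check chosen after the data were seen, the correlation between each channel's signal and the allele effects predicted from genotype was computed over 516 genes with a local LOD of at least 20. Its absolute value, which does not depend on the titles for its sign, was larger in the channel that the titles give the strain on 205 of all 208 arrays (median 0.817, against 0.0963 in the other channel). The array of line QX77 was among the 3 with the larger value in the other channel.

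Intensities were background corrected by normexp with offset 50 and normalised within arrays by loess (limma 3.58.1, R 4.3.3), duplicate spots were averaged, and log2 ratios were turned to strain over reference. Of 44381 spots per array 42964 were not controls. Spots that the software marked as outliers made up 0.526%, and 0.104% of probe values were dropped. A probe was tested if it was well above background in the strain channel on at least 50% of arrays, and each gene was represented by its brightest probe, which left 15556 genes of 18877 with a name. Saturated spots made up a median of 0.36% in the strain channel, with a maximum of 1.45%. Median intensities ran from 28.2 to 329 in green and from 72.7 to 684 in red. The reference channel was well above background at a median of 80.8% of spots, with a range of 38.3% to 91.4%. The number of arrays limits the precision. Arrays fell on 62 slides and 13 scan days.

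Linkage was tested by regression of each gene on the genotype at each marker, with dye orientation as a covariate, and expressed as a LOD. The threshold for a false discovery rate of 5% came from 100 permutations of lines within dye orientation. A linkage was local if the probe lay within the 1.5-LOD support interval extended to the next marker, and distant otherwise. Distant linkages were counted in 52 bins of 2 Mb, and a hotspot had to pass a Bonferroni-corrected Poisson test and the 95th percentile of the fullest bin in the permutations. Arms and centres were set by length, the centre being the middle part of each chromosome from 25% to 75% of its length, and compared by an exact sign permutation test over 6 chromosomes. The loci npr-1, glb-5 and zeel-1 were tested with limma at the nearest marker, with dye orientation as a covariate and Benjamini-Hochberg adjustment at 5%. The npr-1 marker split the lines into 128 N2 and 80 CB4856, that of glb-5 into 126 and 82, and that of zeel-1 into 204 and 4. The npr-1 test found 142 genes higher with N2 and 272 with CB4856, and with Agilent's processed log ratio 189 and 188. Shares have exact binomial (Clopper-Pearson) 95% intervals, and that of distant linkages also has one from 10000 draws of the 52 bins with a distant peak, chosen after the data were seen.

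Gene lists numbered 25: major sperm proteins, other sperm genes, oocyte and early embryo genes, yolk proteins, cuticle collagens, molting, embryo regulators, F-box, MATH/BATH, C-type lectins, chemoreceptors, cytochrome P450, UGT (glucuronosyltransferases), GST (glutathione S-transferases), heat shock, ribosomal proteins, respiratory chain, nuclear hormone receptors, neuropeptides, oxygen and aggregation circuit, lysozymes and antimicrobials, histones, body muscle, intestinal proteases, and male neurons and seminal fluid. Their local linkage was tested by Fisher's exact test and their differences at npr-1 by camera with a preset correlation of 0.01 and, as an alternative, an estimated one, each adjusted over the 25 lists. List scores are means over a list per line, centred within dye orientation, and were compared by Pearson and Spearman correlation with 100000 permutations.

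The comparisons, tests, lists, alternatives and the rule for named genes were set before the data were examined. That rule names the 12 local and 12 distant linkages of highest LOD, 6 genes in each of the 3 fullest bins, the 10 largest differences in each direction outside 2 Mb and the 4 largest within 2 Mb for npr-1, the 3 largest in each direction for glb-5 and zeel-1, and 4 members of each list that passed. The test of lists for distant linkage, the match of arrays to lines and the channel check were chosen after the data were seen.

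The scan was tested on simulated data with 50 genes at each of 4 differences. It found 16%, 40%, 70% and 90% of log2 differences of 0.1, 0.2, 0.4 and 0.8, and 3 of 15356 unchanged genes. Only the simulated genes carried effects, each placed at a marker, and the threshold was set anew. These rates need not hold for the scan of the real data. The test at npr-1 found 38%, 54%, 88% and 98%, that at glb-5 28%, 58%, 90% and 96% with 40 unchanged genes called, and that at zeel-1 0%, 4%, 28% and 60%.

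Alternatives changed the normalisation (Agilent's log ratio, median centring), the filter on dim probes, the trait scale, covariates (none, scan series, slide, 5 principal components), the dye orientation used, the false discovery rate, the definition of local, the domains, bin size, probe choice, marker and set test. Chosen after the data were seen were scan day as a block, arrays with at least 50% of spots well above background, the sign of 1 array turned, and leaving out 10 arrays that matched another line better than their own. No array was left out of the values in the report. Probes without a gene name (564) or a coordinate (6) were not analysed here, and no probe for peel-1 was found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.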

Results

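Messenger RNA was measured in 208 recombinant inbred advanced intercross lines of the nematode Caenorhabditis elegans. Each line is a mosaic of 2 parents, the laboratory strain N2 from Bristol and the wild strain CB4856 from Hawaii, made near homozygous by selfing after rounds of intercrossing. Every line was hybridised once, as young adult hermaphrodites, on a 2-colour Agilent array against a common pool of both parents at mixed stages. The strain RNA carried Cy5 for 52.4% of the lines and Cy3 for the rest. Each array held 42964 spots for 20401 probes, and a median of 80.8% of the spots were well above background in the strain channel, with a range from 11.4% to 92.7%. The genotype of each line was known at 1455 markers. With 1 array per line, a comparison sets lines that carry the N2 allele at a marker against lines that carry the CB4856 allele, and the number of lines on each side limits its precision.

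Expression followed the deposited genotype of its own line better than that of any other line on all but 10 of the 208 arrays. Over 516 genes with a strong local effect, the median correlation between an array and the effects predicted from its line's genotype was 0.909, across genes, which are not independent replicates. On 7 of the 10 arrays the correlation with another line's genotype was above 0.7, from 0.772 to 0.938, against 0.0618 to 0.824 for their own line. The array of line QX77, with Cy3, had a correlation of -0.920 with its own genotype and a median correlation of -0.705 with the other arrays of its dye. The array of line QX183 was well above background at only 11.4% of spots, and that of line QX88 had nearly equal correlations with its own line (0.536) and another (0.544). The thresholds behind these counts were chosen after the values were seen, and all 208 arrays were kept.

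**Figure D1:**
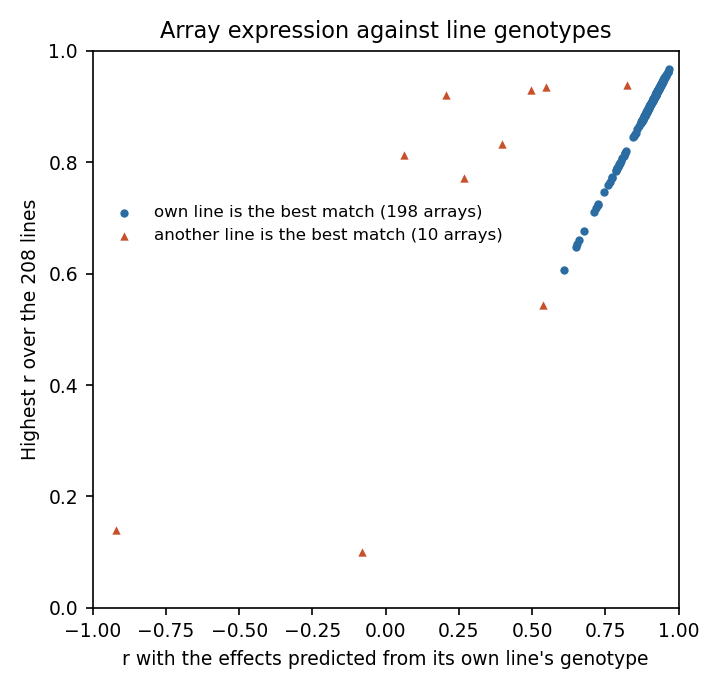
Each point is 1 of the 208 arrays. The horizontal axis gives the correlation, across 516 genes with local linkage, between the array and the effects predicted from its own line's genotype, and the vertical axis gives the highest such correlation over all lines. The own line gave the highest value for all but 10 arrays, 1 of which lies at -0.920, and the median over all arrays was 0.909.

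The N2 allele was unevenly spread over the genome. It reached 98.6% of lines (95% exact binomial interval 95.8 to 99.7) at 2.31 Mb on chromosome I, the neighbourhood of zeel-1 and peel-1, an antidote and toxin pair that kills embryos lacking the element. The mean N2 share over the markers of a chromosome was 73.6% on I, 59.4% on II, 47.4% on III, 56.1% on IV, 58.9% on V and 51.2% on X. The lowest share at any marker was 39.9% (33.2 to 46.9), at 2.66 Mb on chromosome III. The mitochondrial marker carried the N2 allele in 46.6% of lines (39.7 to 53.7). These intervals cover the sampling of lines only, and neighbouring markers are not independent.

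The first comparison asked which genes differ in expression with the allele at some marker. Of 15556 genes tested, 2316 (14.9%) were linked to a marker. For 1614 genes the marker interval held the gene's own probe, here called local, and for 702 it did not, here called distant. Differences are given as N2 minus CB4856 allele on the log2 scale of strain over pool. The strongest local differences were large. F54E2.1 on chromosome V was higher with the N2 allele by 4.56 ± 0.09 (SE), a 23.6-fold difference, with means of 1.32 ± 0.79 (SD) and -3.24 ± 0.45. The glutathione S-transferase gene gst-27 was 13.9-fold higher with the N2 allele (3.80 ± 0.09), the tetraspanin gene tsp-14 14.9-fold (3.90 ± 0.11) and C29F9.14 15.6-fold (3.96 ± 0.12). The cathepsin A homologue ctsa-4.2 (3.18 ± 0.08), the BTB-domain gene btb-14 (3.19 ± 0.08), R07C12.2 (3.19 ± 0.09), F10E7.2 (2.53 ± 0.07), the F-box gene fbxa-65 (2.52 ± 0.07) and eelo-2 (1.65 ± 0.04) were also higher with N2. Of the 12 local genes with the highest LOD, the log10 odds of linkage, only wdr-5.2 (-1.48 ± 0.04), a homologue of the WD-repeat protein WDR5, and R08F11.1 (-2.32 ± 0.07) were higher with CB4856. The probe of R07C12.2 was well above background on 99.1% of arrays of N2 lines and 28.6% of arrays of CB4856 lines, so the size of its difference is not exact. A second probe of tsp-14 had the same direction but a LOD of 11.9 at the gene's peak, against 86.9 for the probe used. The size of the tsp-14 difference therefore depends on the probe.

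**Figure D2:**
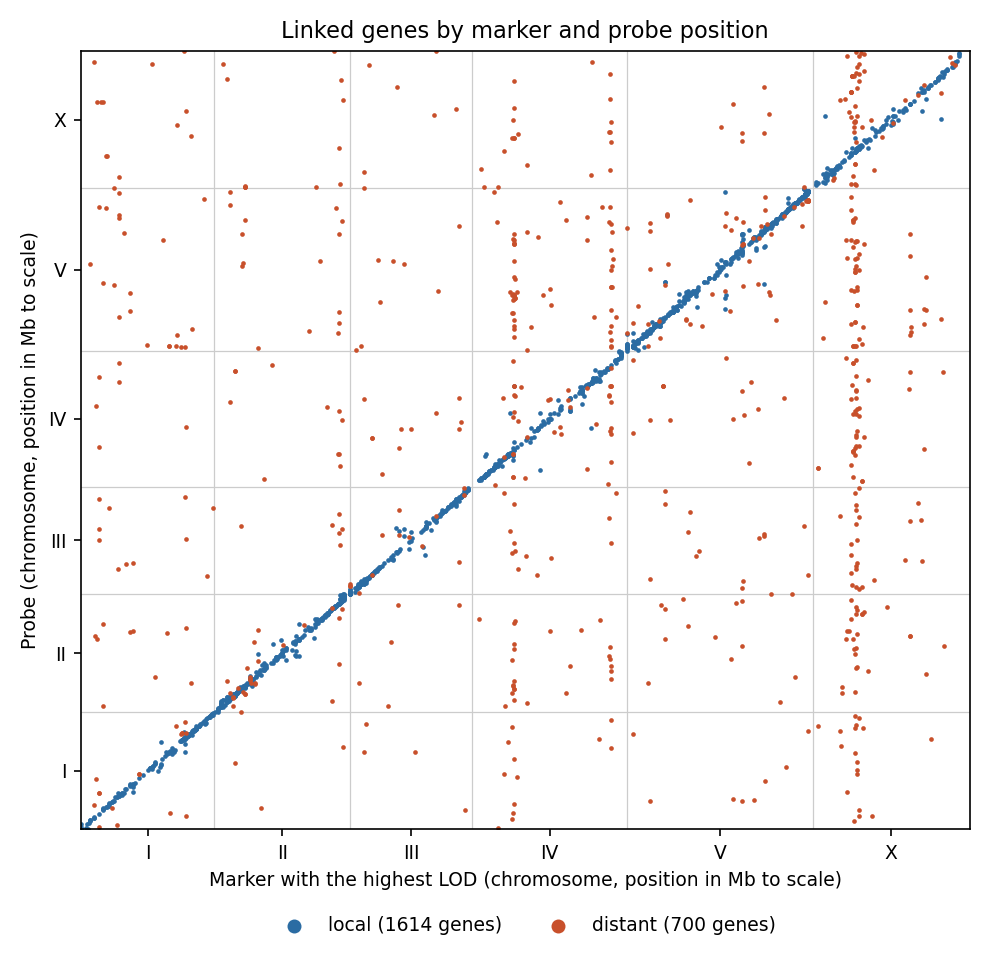
Each point is a linked gene, at the position of the marker with its highest LOD (horizontal) and of its probe (vertical), with the 6 nuclear chromosomes in order and drawn to scale in Mb. Local genes, 1614 in blue, follow the diagonal, and distant genes, in orange, gather in columns of which the one on X is the densest. The 2 genes linked to the mitochondrial marker are not drawn.

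Across all local genes the N2 allele was the higher one in 63.4% (95% exact binomial interval 61 to 65.7), 1023 genes against 591. The share was 68.9% at a LOD of at least 10, 72.9% at a LOD of at least 20 and 78.4% (71.1 to 84.7) at a LOD of at least 50. Of the distant genes 289 were higher with N2 and 413 with CB4856, a share of 41.2% (37.5 to 44.9 with genes taken as independent, 32 to 54.4 with the peaks of a bin drawn together). With slide as a block the distant share was 48.5%, and with 5 principal components as covariates it was 50.7%. The direction of every value rests on the dye that the sample titles give the strain, and the channel labels of the same samples state the opposite dye. In a check chosen after the data were seen, over the 516 strongest local genes the median size of the allele difference was 0.98 log2 in the channel that the titles give the strain and 0.10 in the other, for strains in Cy5, and 0.89 and 0.08 for strains in Cy3. Local differences had a median size of 0.37 and distant ones of 0.27, and 266 local and 39 distant genes differed by at least 1 log2 unit. More than 50% of the variance between lines was explained for 336 local and 31 distant genes, with medians of 22% and 12% over all genes of each kind. Agilent's processed log ratio gave 1437 linked genes, 312 of them distant, and 5 principal components as covariates gave 4851 and 2264. Reassigning genotypes to lines within a dye orientation gave a mean of 115.7 linked genes over 100 permutations, which set the LOD threshold of 3.94 at a false discovery rate of 5%. In 14 of them over 200 genes were linked, and the highest count was 668.

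The distant linkages of highest LOD included a pair of neighbours. F55G11.7 and F55G11.6, next to each other near 12.96 Mb on chromosome IV, were linked to 4.04 Mb on chromosome V and were 34-fold and 31.4-fold higher with the CB4856 allele there (-5.09 ± 0.13 and -4.97 ± 0.13). C39B5.10 on III was linked to I at 14.27 Mb (-3.44 ± 0.12), C14C6.12 on V to III at 1.24 Mb (-3.72 ± 0.16), and the trypsin-like gene try-11 on V to I at 5.52 Mb (-1.52 ± 0.08), all higher with CB4856. Y20F4.5 on I and K08D10.1 on IV were both linked to IV at 4.63 Mb and were higher with N2 (1.80 ± 0.07 and 1.58 ± 0.07). For 29.5% of the distant genes the marker lay on the gene's own chromosome. Among these were R03H10.6 (-3.05 ± 0.08, probe at 4.172 Mb, just past its interval of 3.968 to 4.145 Mb), the F-box genes fbxa-58 (-1.76 ± 0.07) and fbxa-54 (-1.32 ± 0.06), Y17D7A.2 (-1.52 ± 0.07) and T20D4.9 (0.66 ± 0.03), whose probe was well above background on 25.8% of arrays of CB4856 lines. A probe that matches a related copy elsewhere would give the same pattern, so the members of gene families among these are uncertain. The mitochondrial marker was linked to F56C3.7 (0.17 ± 0.01) and F52F10.2 (0.81 ± 0.14), and no probe of a mitochondrial gene was among those tested.

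Local linkage was more frequent on chromosome arms than in centres, a comparison that sets regions of high recombination against regions of low recombination. On the arms 1110 of 6566 genes (16.9%) had a local linkage, and in the centres 504 of 8990 (5.61%), a ratio of 3.02. The arm rate was highest on V, 25% against 8.0% in its centre, and on II, 21.9% against 6.38%. On III the rates were 16.1% and 3.41%, on IV 14.7% and 4.94%, and on I 12.7% and 4.08%. Chromosome X stood apart, with 6.58% on its arms and 6.12% in its centre. The difference had the same sign on all 6 chromosomes (2-sided exact sign permutation test, p = 0.03125, the smallest that 6 chromosomes can give). It stopped passing in 3 alternatives, each with p = 0.0625 and a ratio of at least 2.24. Distant linkage affected 5.24% of arm genes and 3.98% of centre genes.

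Gene families differed in how often their members had a local linkage, tested by 2-sided Fisher's exact test against all other genes for 25 lists fixed before the data were examined. The test takes genes as independent, but members that lie close together can share a marker, so its p-values can be too small. Among MATH/BATH genes, which hold substrate adaptors of ubiquitin ligases, 43 of 69 (62.3%) were local, 36 of them higher with N2 (adjusted p = 3.4e-24). On chromosome II math-27 (4.18 ± 0.13), math-3 (3.22 ± 0.11), math-41 (2.54 ± 0.09) and math-26 (2.36 ± 0.08) shared 1 marker at 1.75 Mb and were all higher with N2. Of the F-box genes 74 were local (38.1%, adjusted p = 1.0e-23), with fbxa-60 (2.59 ± 0.09), fbxa-207 (2.44 ± 0.09) and fbxa-64 (1.82 ± 0.06) as examples. Of the nuclear hormone receptors, which are transcription factors, 48 were local (24.5%, adjusted p = 6.5e-08), among them nhr-156 (1.44 ± 0.05), nhr-116 (1.02 ± 0.04), nhr-225 (0.88 ± 0.03) and nhr-123 (0.77 ± 0.03). Cytochrome P450 genes were local in 16 of 67 (23.9%, adjusted p = 0.0063), among them cyp-34A2 (1.19 ± 0.09), cyp-33C4 (0.70 ± 0.05), cyp-33A1 (0.58 ± 0.05) and cyp-33C6 (0.48 ± 0.03). Of the C-type lectins 29 were local (19.1%, adjusted p = 0.0048), including clec-10 (4.38 ± 0.14), clec-233 (1.03 ± 0.06), clec-150 (0.67 ± 0.05) and clec-194 (0.62 ± 0.03). With 5 principal components as covariates the P450 and lectin lists no longer passed (adjusted p = 0.079 and 0.350), nor did the lectins with Agilent's processed log ratio (adjusted p = 0.062). In lines with CB4856 the probe was well above background on 17.5% of arrays for math-3, 34.9% for math-41, 26.4% for fbxa-60, 31.8% for fbxa-207, 31% for nhr-156, 12.4% for nhr-225, 19.1% for clec-10, 4.88% for clec-233 and 27.1% for clec-194, so the sizes of these differences are not exact.

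Chemoreceptor genes and cuticle collagens were local less often than other genes. Of the 366 chemoreceptor genes bright enough to test, out of 1300 on the array, 9 (2.46%) were local (adjusted p = 6.5e-08), including srw-85 (1.40 ± 0.12), srx-58 (0.26 ± 0.03), srh-129 (0.06 ± 0.01) and srt-7 (-0.23 ± 0.02). The probe of srw-85 was well above background on 16.7% of arrays of CB4856 lines, so the size of its difference is not exact. Dim probes can hide small differences, and that of srh-129 was well above background on 59.2% of arrays of N2 lines and 52.6% of CB4856 lines. Low signal was not separated from a lower rate of linkage for the chemoreceptor genes. Only 2 collagen genes (1.30%) were local (adjusted p = 6.9e-05), col-182 (-1.69 ± 0.17) and col-142 (-0.78 ± 0.18), whose probes were saturated on 14.9% and 35.6% of arrays. Linkage of col-142 was lost under several alternatives. The lists differ in where they lie: 85.5% of MATH/BATH and 88.1% of F-box genes were on arms. Within arms alone 72.9% of MATH/BATH, 39.2% of F-box, 35.9% of nuclear hormone receptor, 38.2% of cytochrome P450, 24.2% of C-type lectin, 1.87% of chemoreceptor and 0 of 53 collagen genes were local, against 16.9% of all arm genes. In centres it was 0 of 10 MATH/BATH, 30.4% of F-box, 7.6% of nuclear hormone receptor and 9.09% of cytochrome P450 genes. There it was also 10.5% of C-type lectin, 3.29% of chemoreceptor and 1.98% of collagen genes, against 5.61% of all centre genes. When arms and centres were taken separately, the odds ratio fell from 5.53 to 3.52 for F-box, 14.6 to 11.3 for MATH/BATH, 2.86 to 2.46 for nuclear hormone receptor, 2.73 to 2.62 for P450 and 2.06 to 1.66 for lectin genes. Members of these families can resemble each other closely, and probes that cross-hybridise would blur which member differs.

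The other 18 lists did not pass after adjustment. No member was local among 26 major sperm proteins, 32 oocyte and early embryo genes, 6 yolk proteins and 8 genes of male neurons and seminal fluid. The local share was 5.17% for 58 other sperm genes, 2.99% for 67 molting genes, 11.1% for 27 embryo regulators, 20.3% for 64 UGT genes, 20.5% for 39 GST genes, 8.33% for 12 heat shock genes and 1.61% for 62 ribosomal protein genes. It was 11.9% for 42 respiratory chain genes, 7.14% for neuropeptide genes, 20% for 20 genes of the oxygen and aggregation circuit and 7.69% for 52 lysozyme and antimicrobial genes. It was 2.70% for 37 histone genes, 3.85% for 26 body muscle genes and 20.8% for 24 intestinal protease genes. Adjusted p-values of UGT and ribosomal protein genes were 0.057 each.

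Distant linkages gathered most in the bin from 4 to 6 Mb on chromosome X, the region of npr-1, which held 21.2% of them. An even spread would put 14 genes in a bin. In this one 35 genes were higher with N2 and the other 76.5% with CB4856. With 5 principal components as covariates the fullest bin was instead that from 2 to 4 Mb on V, with 284 genes in place of 12. The one on X then held 274 of 2264 distant linkages. The bin on X held 54 of 312 distant linkages with Agilent's processed log ratio, 63 of 365 with median centring and 83 of 546 with slide as a block. It held 48 of 282 with strains in Cy5 alone and 46 of 286 with strains in Cy3 alone. The genes of highest LOD in the bin on X were capa-1, which encodes a neuromedin U-like peptide precursor (-0.47 ± 0.04), nssp-42 (-0.43 ± 0.04), the neuropeptide genes nlp-46 (-0.33 ± 0.03), flp-21 (-0.34 ± 0.03) and flp-27 (-0.52 ± 0.05), and nspc-18 (-0.91 ± 0.09). The probe of capa-1 lies in this bin itself, at 5.92 Mb, outside its marker interval of 4.75 to 5.23 Mb but where neighbouring alleles travel together. The next bins lay on IV, from 4 to 6 Mb with 72 genes (58 higher with CB4856) and from 14 to 16 Mb with 49 genes (41 higher with N2). The first held the lectin genes clec-3 (-1.09 ± 0.11) and clec-2 (-0.85 ± 0.09), K08F11.2 (1.06 ± 0.05), whose own probe lies in that bin at 4.18 Mb, and rmd-5 (0.36 ± 0.04). The second held Y49G5A.1 (1.60 ± 0.15), the aspartyl protease gene asp-12 (1.47 ± 0.19), Y73B6A.3 (0.62 ± 0.06), drd-1 (0.50 ± 0.06), K10D11.6 (0.46 ± 0.05) and fbxc-44 (0.36 ± 0.04).

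No bin passed both criteria set for a hotspot, a Poisson test and the permutations. Of 52 bins, 4 passed the Poisson test after Bonferroni correction (adjusted p = 5.3e-95 for X, 2.5e-26 and 1.3e-11 for IV, and 0.048 for 20 genes from 14 Mb on II). When genotypes were reassigned to lines, the fullest bin held a median of 17 genes, but its 95th percentile was 405 and 13 of 100 permutations had a bin as full as the one on X. Without the array of line QX183 that percentile fell to 41.7% of 405, still above the bin on X, and 9 permutations had a bin as full. The count of hotspots was 0 in all 20 alternatives as well.

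**Figure D3:**
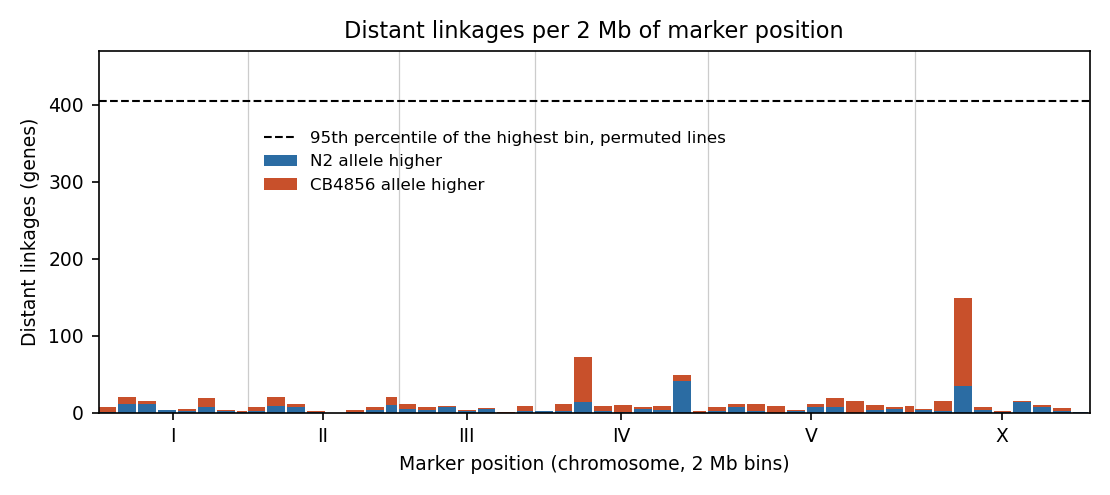
Bars give the number of genes with a distant linkage per 2 Mb of marker position, stacked by the allele with the higher expression, and the dashed line gives the 95th percentile of the fullest bin over 100 permutations, 405 genes with all arrays and 41.7% of that without the array of line QX183. The bin from 4 to 6 Mb on X is the tallest, with 21.2% of the distant linkages, and lies below both.

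The second comparison asked what differs with the allele at npr-1, a neuropeptide receptor gene whose N2 form suppresses aggregation, between 80 lines with CB4856 and the other 61.5% with N2 at the nearest marker on X, 13.5 kb from the probe. Of 15556 genes 414 differed, 34.3% higher with N2 and the other 272 higher with CB4856 (limma, Benjamini-Hochberg adjusted p under 0.05). With Agilent's processed log ratio 50.1% were higher with N2. Outside 2 Mb of the locus C01C10.2 rose most with N2 (1.26 ± 0.11, adjusted p = 1.7e-19), followed by nspe-2 (0.87 ± 0.12), K11H12.4 (0.80 ± 0.14), nspc-7 (0.66 ± 0.11), the fatty acid desaturase gene fat-5 (0.48 ± 0.14), cest-1.2 (0.45 ± 0.09), K11H12.3 (0.45 ± 0.09), the methionine aminopeptidase gene map-2 (0.45 ± 0.10), eelo-2 (0.45 ± 0.12) and the glutathione S-transferase gene gst-4 (0.41 ± 0.08). The strongest linkage of eelo-2 was local, on IV at 16.78 Mb (1.65 ± 0.04). The test at npr-1 had no term for that marker, so the 2 were not separated for eelo-2. Among those higher with CB4856, 5 belonged to the nematode-specific peptide family C: nspc-18 (-0.91 ± 0.09, adjusted p = 1.0e-15), nspc-19 (-0.85 ± 0.09), nspc-10 (-0.85 ± 0.09), nspc-16 (-0.84 ± 0.09) and nspc-17 (-0.80 ± 0.09). C36C5.14 (-0.90 ± 0.23), C36C5.15 (-0.86 ± 0.23), C36C5.12 (-0.85 ± 0.16), clec-60 (-0.78 ± 0.14) and the lysozyme gene lys-7 (-0.74 ± 0.12) were also higher with CB4856.

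Close to the locus tsp-14 (3.73 ± 0.14), the mannosidase gene aman-1 (1.51 ± 0.06), the kinase gene cst-2 (1.0 ± 0.06) and the immunoglobulin-domain gene zig-6 (-0.73 ± 0.08) differed most. Second probes of tsp-14 and cst-2 had the same direction at the gene's peak with lower LODs (11.9 and 19.5, against 86.9 and 57.7). The sizes of these 2 differences therefore depend on the probe. The npr-1 gene itself, probe at 4.77 Mb, did not pass: -0.03 ± 0.02, adjusted p = 0.626. Of the 414 genes 55 lay within 2 Mb of the locus, where neighbouring alleles travel together, and 273 lay on other chromosomes. The count was 881 with 5 principal components as covariates, and with slide as a block it was 47.8% of 414.

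Neuropeptide genes were lower with the N2 allele at npr-1 as a group. Of those tested, 44 (39.3%) fell and none rose over all genes tested, and 54 fell when adjusted over the list alone, with a median difference of -0.08 and a mean of -0.12. The largest were flp-8 (-0.70 ± 0.08, adjusted p = 5.2e-13), nlp-4 (-0.56 ± 0.15), flp-27 (-0.51 ± 0.05) and flp-14 (-0.47 ± 0.06), all outside 2 Mb of the locus. The set test gave an adjusted p of 2.1e-43 (camera, preset correlation, 25 lists), and an adjusted p = 0.00056 with an estimated correlation. Over the alternatives the adjusted p ran from 1.9e-47 to 0.00056. The mean difference was -0.11 ± 0.03 (SE) in the 80.8% of arrays read with the older scanner software and -0.14 ± 0.05 in the 19.2% read with the newer one.

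**Figure D4:**
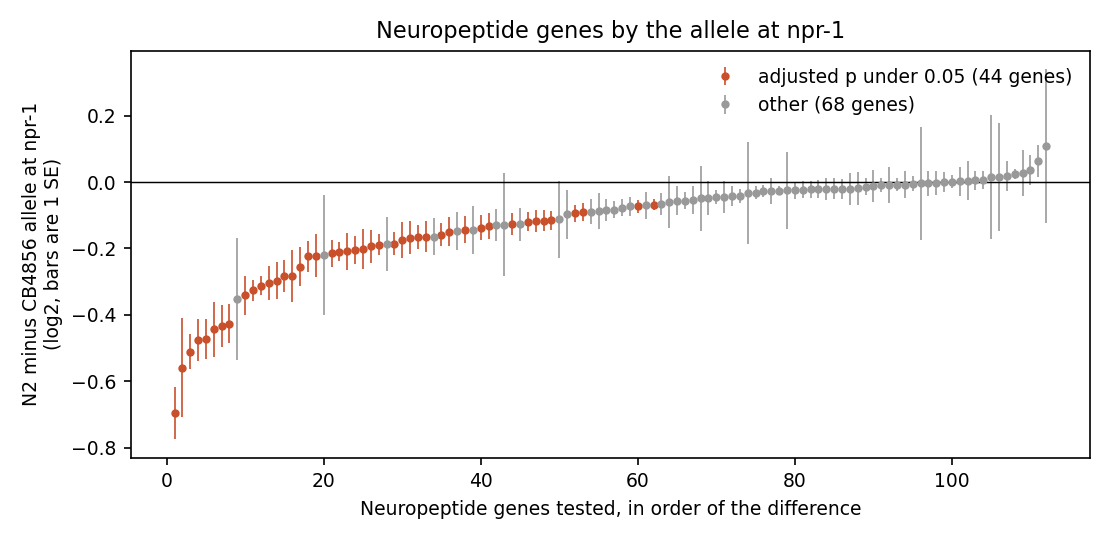
Each point is a neuropeptide gene, placed by its difference between lines with the N2 and the CB4856 allele at npr-1 (log2, bars are 1 SE) and ordered by that difference. The 44 genes with an adjusted p under 0.05 are in orange, and all 44 lie below 0.

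Other lists passed only with the preset correlation. Body muscle genes were lower with N2 (median -0.09, adjusted p = 1.9e-08, but adjusted p = 0.283 with an estimated correlation), with 5 of 26 past the threshold over all genes and 8 when adjusted over the list alone. Examples were the troponin genes tnt-2 (-0.23 ± 0.05) and tni-3 (-0.20 ± 0.05) and the tropomyosin gene lev-11 (-0.19 ± 0.04), and the paramyosin gene unc-15 had -0.21 ± 0.07 with adjusted p = 0.110. This list's median turned to 0.01 with median centring and no loess (adjusted p = 0.994), and with Agilent's processed log ratio the adjusted p was 0.543, the alternatives running from 2.0e-10 to 0.994. The oxygen and aggregation circuit was lower with N2 (median -0.02, adjusted p = 2.4e-06, but adjusted p = 0.119 with an estimated correlation) through 3 of 20 genes, flp-21 (-0.33 ± 0.03), a ligand of the receptor, flp-18 (-0.28 ± 0.08), which lies within 2 Mb, and the guanylate cyclase gene gcy-33 (-0.11 ± 0.03). The same 3 passed when adjusted over the list alone, and ocr-2 had 0.10 ± 0.11. Both flp-21 and flp-18 are neuropeptide genes, so the result of this list is not separate from that of the neuropeptide genes. MATH/BATH genes leaned upward (median 0.05, adjusted p = 0.0497, and adjusted p = 0.948 with an estimated correlation), although math-38 (-0.62 ± 0.11) and math-45 (-0.50 ± 0.11), the only members past the threshold, fell. The values of math-27 (0.51 ± 0.30) and math-3 (0.42 ± 0.23) did not pass, and the list's median was -0.01 with 5 principal components as covariates. The remaining 21 lists had adjusted p-values from 0.091 for yolk proteins to 0.923 for embryo regulators.

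At glb-5, a globin gene of oxygen-sensing neurons on chromosome V, 82 lines carried the CB4856 allele and the other 60.6% the N2 allele. Expression of glb-5 itself was lower with N2 by a difference of -0.50 ± 0.03 (adjusted p = 8.3e-44), and its probe was well above background on 23.8% of arrays of N2 lines and 93.9% of arrays of CB4856 lines, so its size is not exact. The test found 66 genes higher with N2 and 72 higher with CB4856, 64 of all these within 2 Mb and 17 on another chromosome (limma). Largest upward were F54E2.1 (1.35 ± 0.32), K11D12.7 (1.14 ± 0.09) and fbxa-65 (1.0 ± 0.18), and largest downward were F55G11.7 (-2.43 ± 0.34), F55G11.6 (-2.40 ± 0.33) and ppt-1 (-1.43 ± 0.13), which encodes a palmitoyl-protein thioesterase. The strongest linkage of F54E2.1, fbxa-65 and both F55G11 genes was to other markers of chromosome V, at 2.78, 3.26 and 4.04 Mb. With 5 principal components as covariates 344 genes differed.

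At zeel-1 only 4 lines carried CB4856, and 98.1% carried N2. All 4 genes that passed were higher with CB4856: nspd-8 (-1.19 ± 0.18, adjusted p = 4.8e-06) and F32B5.3 (-0.91 ± 0.16), both within 2 Mb, F20B6.6 on X (-0.75 ± 0.16) and F46F5.12 on II (-0.21 ± 0.04), the last named after its value was seen (limma, n = 4 lines with CB4856). An unadjusted p under 0.05 was reached by 483 genes. The zeel-1 probe was well above background on 8.65% of arrays and was not tested, and no probe of peel-1 was found. The alternatives gave from 0 to 17 genes, so the count depended on the setting.

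The third comparison asked whether germline and cuticle genes move together across lines. Lines with higher sperm scores, the mean over 84 sperm genes, also had higher oocyte and early embryo scores (Pearson r = 0.381, Spearman rho = 0.322, permutation p = 1.0e-05 each, the smallest they can give, adjusted p = 1.5e-05 over 3 relations, n = 208). The r was 0.465 without the 2 lines farthest from the median, 0.539 with strains in Cy5 and 0.193 with strains in Cy3, where it did not pass (p = 0.056). It was 0.386 and 0.363 in the 2 scanner software groups, and among 12 scan days with at least 6 arrays it ran from -0.115 to 0.918. Collagen scores rose with sperm scores (r = 0.471, rho = 0.673, p = 1.0e-05 each, the smallest possible, adjusted p = 1.5e-05), with r = 0.439 without the 2 farthest lines, 0.456 and 0.492 by dye, 0.439 and 0.652 by software group, and 0.275 to 0.837 within scan days. Yolk and sperm scores had r = 0.098 and rho = 0.098 (p = 0.160 and 0.159). Their r was 0.19 without the 2 farthest lines, 0.272 with strains in Cy5 and -0.065 with strains in Cy3. By software group it was 0.120 and 0.013, and within scan days it ran from -0.285 to 0.526. The first principal component of all genes held 36.8% of the variance and the second 24%. The first had an absolute r of 0.933 with the oocyte score and 0.867 with the yolk score, and the second 0.933 with the sperm score and 0.691 with the collagen score.

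Against the mixed-stage pool, sperm genes were high and yolk genes low in the lines, with the direction of every ratio taken from the titles. Values are mean log2 strain over pool ± SD over 208 lines, with no test, since the pool is a single reference. Major sperm proteins stood at 1.59 ± 1.42 and other sperm genes at 1.27 ± 0.79, with all 26 and 55 of 58 genes higher in the lines. Yolk proteins stood at -2.54 ± 1.29 and oocyte and early embryo genes at -1.46 ± 0.95, every member lower. Body muscle genes were at 0.61 ± 0.22, molting genes at 0.49 ± 0.67, cuticle collagens at 0.48 ± 0.52 (76% of collagen genes higher in the lines), UGT genes at 0.38 ± 0.19 and heat shock genes at 0.35 ± 0.44. A check of direction set before the data were examined held that the pool has more larval cuticle and embryo RNA than young adults. Embryo regulators were lower in the lines (-0.13 ± 0.13), but collagens were higher, so that check did not settle the direction. The level of embryo regulators was -0.38 with Agilent's processed log ratio and -0.16 with median centring. Ribosomal protein genes were at -0.12 ± 0.18 and histones at 0.05 ± 0.23, and both changed sign with Agilent's processed log ratio (0.06 and -0.19) and with median centring (0.07 and -0.15). The mean ratios of the genes in the 2 dye orientations, turned by the titles, had r = 0.97 across genes, which are not independent replicates. Turning by the channel labels would give the same r, so it does not bear on the direction.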

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

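The tests of the arrays' identity and dye, that of normalisation, the count of second probes by gene and all counts over reassigned genotypes were chosen only after the result was seen.

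A group of 7 arrays followed the genotype of another line. A mislabelled sample is a candidate explanation: all 7 had the same other line as best match on chromosomes I to III and, separately, on IV, V and X. They were picked by a correlation above 0.7 with that line over all 516 genes, so this agreement is partly built in. Low signal is argued against, since 0 of the 7 lay under the 5th percentile of spots well above background (71.8%), and their median was 80.7%. The array of line QX77 had r = -0.920 with its own genotype effects, which is consistent with a dye noted the wrong way round for that array, and its 2 channels had r = -0.211 in the channel its title gives the strain and 0.829 in the other. No biological explanation was tested for these arrays.

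Local linkages had an excess with the N2 allele higher. A normalisation that favours N2 cannot be told apart from the other explanations: the N2 share among distant linkages was 41.2%, but its 95% interval reached 54.4% with the peaks of a bin drawn together, and the share was 50.7% with 5 principal components. The excess of local linkages stayed with Agilent's ratio (66.4%) and median centring (65.6%). Probes designed on N2 that bind the CB4856 sequence less well cannot be told apart from a difference in expression: a second probe of the gene shared the linkage in 69% of 29 probes with N2 higher and 62.5% of 8 with CB4856 higher, a difference of 6.47 points, and counted by gene (25 and 7) the difference was 12.9 points with an interval from -26 to 53.7. The small number of second probes keeps this open, and a true difference in expression between the parents' alleles was not tested apart from it.

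Neuropeptide genes were lower with the N2 allele at npr-1. A difference in developmental age is argued against as the whole cause, since 96% of the difference was left with the sperm, oocyte, yolk and collagen scores as covariates, as is a difference between scan days, with 110% left. More RNA from neurons in lines with CB4856 cannot be told apart from a change within neurons: synaptic vesicle genes had 47% of the neuropeptide difference (-0.06 ± 0.03, 24 genes, interval -0.12 to 0.00), and dense-core vesicle genes -0.14 ± 0.04 (12 genes). The width of the synaptic vesicle interval keeps it open. An effect of the alleles at or near npr-1 on neuropeptide expression may also account for it and, with linked variants in the same interval, was not tested apart.

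Genotypes were reassigned to lines within dye orientation to give 100 splits, the real one included. Only the real split reached 2316 linked genes (highest other 668), 1614 local linkages (highest other 10) and 702 distant linkages (highest other 665). The LOD threshold came from these same permutations, with a mean of 115.7 linked genes, so few of them could reach 2316. That comparison therefore cannot exclude chance for the number of linked genes. Local and distant linkages are parts of that number, so the same limit holds for their counts, and the margin for distant linkages was narrow. The threshold does not set where linkages fall. In the real split 69.7% of linked genes were local, while the highest local count in another split was 10. Few splits were as large at npr-1 (3, 414 genes, highest other 914) and glb-5 (2, highest other 1709), which argues against chance. Since single splits went far above the real counts, chance is not excluded there. These counts include genes near the locus: 55 at npr-1 and 64 at glb-5 lay within 2 Mb. For the fullest bin 14 splits were as large (highest other 483) and for zeel-1 28 (4 against 6550), so chance cannot be excluded for either. Splits that call over 2 times the real count arose at all 3 loci. Without the array of line QX183 and with new shuffles, 3 splits were as large at npr-1 (427, highest other 4149), 1 at glb-5 (highest other 0) and 21 at zeel-1 (highest other 2.34% of 6550). That array alone therefore does not account for such splits at npr-1, and no other source of them was tested.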

How the results depend on the processing

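Scan day as a block, the filter on arrays, the sign of 1 array and leaving out 10 arrays were chosen only after the data were seen. The local share with N2 higher kept its direction in all 19 alternatives (59.7% to 67.5%), hotspots stayed at 0 in 20, and the highest N2 share was 98% to 99.1%. The arm to centre ratio ran from 2.24 to 4.07, and its test no longer passed with probes well above background on at least 90% of arrays (2.80), rank-based scores (2.84) or 5 principal components (2.24), with p = 0.0625 each. Agilent's processed log ratio gave 1437 linked genes, 312 distant linkages, 12 lists at npr-1 in place of 4, and 0 genes at zeel-1 in place of 4. Median centring gave 1483 linked, 365 distant, 13 lists at npr-1 and 2 genes at zeel-1, and turned the body muscle median at npr-1 to 0.0113. With 5 principal components there were 4851 linked, 2587 local and 2264 distant linkages, 881 genes at npr-1, 344 at glb-5 and 17 at zeel-1, and the MATH/BATH median at npr-1 turned to -0.0101. The distant share with N2 higher was 45.2% with Agilent's ratio and 48.5% with slide as a block, and it crossed to 50.7% with 5 principal components. Slide as a block gave 47.8% as many genes at npr-1 (2.0e+02) and 2 at zeel-1. Scan day as a block gave 11 lists for local linkage in place of 7 and 11 at npr-1. An estimated correlation left 1 list at npr-1. At zeel-1, 483 of 15556 genes had an unadjusted p under 0.05 in the values reported (limma), which is below 5%. Rank-based scores gave 0 genes at zeel-1, the 90% filter 1 and the marker on the other side 8. For these changes the cause was not tested. Fewer arrays limit the single dye orientations: Cy5 gave 1358 linked, 282 distant, 1.3e+02 at npr-1 (31.9% of 414) and 63 at glb-5, and Cy3 gave 1284 linked, 998 local, 286 distant, 1.6e+02 at npr-1 (38.2%), 51 at glb-5, 1 at zeel-1 and r = 0.193 for oocyte and sperm scores. Too few lines with CB4856 at zeel-1 had strains in Cy5 for a value. A stricter false discovery rate of 1% gave 370 distant linkages by its construction. Among named genes 974 linkage values kept their side of the threshold and 10 no longer passed (7 of them col-142), and at npr-1 644 kept it and 50 no longer passed. Of the levels against the pool, 45 moved by less than 1 SD and 5 by more, among them histones and ribosomal proteins, which turned sign. Signal over background limits dim genes such as zeel-1, well above background on 8.65% of arrays.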

Other observations

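The test of lists for distant linkage and the test of neighbouring genes were chosen only after the result was seen.

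Lists also differed in distant linkage. Neuropeptide genes had one in 30 cases (26.8%, Fisher's exact test adjusted over 25 lists, p = 2.8e-14), 28 of them higher with CB4856, 25 with the peak on X and 20 with it between 4 and 6 Mb there. Histone genes had one in 12 of 37 (32.4%, adjusted p = 5.3e-07), 11 of them with the peak on III. Intestinal proteases had one in 7 of 24 (29.2%, adjusted p = 0.00054), cytochrome P450 genes in 11 of 67 (16.4%, adjusted p = 0.00093) and C-type lectins in 18 (11.8%, adjusted p = 0.00093), 16 of these higher with CB4856, and UGT genes (8 of 64) and GST genes (6 of 39) had adjusted p = 0.028 each. Fisher's test takes members as independent, although many shared a peak. With genotypes reassigned to lines, which keeps members together, none of 99 other splits put any of these 7 lists as far above other genes. Neuropeptides stood 22.4 points above (highest other 5.93) and histones 28 (highest other 8.14). The permutations had a median of 67 linked genes in all, against 702 distant ones in the real data. With so few linked genes, gaps of that size in points were hard to reach, so this comparison cannot tell whether the lists are enriched.

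Some strong distant linkages fell on neighbouring genes. F55G11.6, F55G11.7 and dod-22 on IV shared a peak at 4.04 Mb on V, and AC8.3, AC8.4 and AC8.7 on X shared one at 3.40 Mb on II. A hypothesis is that such segments may lie elsewhere in the CB4856 genome, whose sequence was not analysed here. Of 36 linkages to another chromosome with a LOD of at least 20, 8 had a neighbour within 20 kb with the same peak, but these include the F55G11 genes that prompted the test, and without those and dod-22 it was 5 of 33 (p = 0.0092 over 10000 shuffles of the peaks, mean 1.30, highest 7). The 5 include AC8.3, AC8.4 and AC8.7, which share 1 peak but were counted separately. Neighbours that share a distant variant without a moved segment would give the same count, so it does not decide the hypothesis. The first form of the test also took peaks on the gene's own chromosome and was narrowed to other chromosomes after its result was seen.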
